A study of Gallus gallus with 12 samples.

How the data were processed

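Skin was dissected from untreated White Leghorn chicken embryos of 6 groups, with 2 libraries per group, and total RNA in Trizol was made into TruSeq RNA V2 libraries, per the labels. The groups were dorsal skin at E7 and E9, thigh and wing skin at E9, all labelled as feather, and tarsometatarsal skin at E9 and E11, labelled as scale. Sample titles call all of these samples dermis, while tissue labels call them skin, the word used here. Nothing says that replicates came from separate embryos, so p-values may measure technical spread alone. Nothing says that replicate numbers pair samples across groups, and they were not used as pairs. Differences between replicates 1 and 2 correlated at -0.14 to 0.34 between groups, highest for dorsal E9 with scale E11, which leaves some pairing possible.

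The deposited table held 12297 rows and 12 columns of signal, as CPM, read counts scaled so that the denominator was an effective library size, with no column left unmatched to a sample. Per the submitters' processing notes TopHat2, Partek, HTSeq and edgeR and the chicken build galGal4 were used by the authors, with no version, role or order given. In all 12 libraries 100.0% of values up to 100 were whole multiples of 1 read within 0.0055 printed units, which allowed reads to be recovered. A library held 13164609 to 20641980 reads, and 1 read was worth 0.0475 to 0.0736 CPM. The limit that a count of 0 allows, 3 reads, was 0.143 to 0.221 CPM per library, for counting error only, since reads without molecular identifiers are not independent molecules. The lowest 2nd highest value of any row was 0.97 CPM, so that low rows were absent from the table. Rows are versioned Ensembl transcripts with a gene symbol; 1300 had a bare identifier in place of a symbol, and 317 shared a symbol with another row and are named by identifier in the tables. The table holds no coordinates, and a reference list of gene names and synonyms was used only to match list members.

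Values were analysed as log2(CPM + 1), so that fold changes of genes at low CPM are understated. Rows with at least 1 CPM in at least 2 libraries were tested, which kept 12277 and removed 20. A linear model with 1 mean per group was fitted in limma with a mean-variance trend in the moderated variances (6 residual and 6.95 prior degrees of freedom), and tests were two-sided. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 within each of 12 contrasts, 3 of them main ones: scale E9 against the mean of dorsal, thigh and wing E9, dorsal E9 against E7, and scale E11 against E9. The other 9 were scale E9 against each feather region, the feather regions against each other, scale E9 against dorsal E7, scale E11 against dorsal E9, and the change with age in scale skin minus that in dorsal skin. The difference between the ages of those intervals is part of the last contrast.

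Gene lists of at least 3 measured members, 31 in all, were tested in limma's camera with a preset inter-gene correlation of 0.01, and again with the correlation estimated. Of 93 list tests in the main contrasts 39 passed, and 37 of these were lost with an estimated correlation; the remaining ones were dermal condensation and smooth muscle and pericyte markers in dorsal skin with age. The lists were study regulators, limb identity, anterior HOX genes (paralog groups up to 8), posterior HOX genes (the later groups), dorsal and trunk dermis, and dermal condensation. Pathway and process lists were the WNT, BMP and TGF-beta, FGF, hedgehog, NOTCH, EDA and retinoic acid pathways, cell cycle, immediate early and stress genes, hypoxia and glycolysis, epidermal barrier and keratinization, and W-linked genes. Markers were those of keratinocytes, dermal fibroblasts and matrix, muscle, cartilage, tendon, bone, red blood cells, endothelium, macrophages and leukocytes, Schwann cells, melanocytes, neurons, and smooth muscle and pericytes. Groups, contrasts, lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. A few genes that met the rule for named genes are not reported here.

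Named genes were the 12 with the largest fold change in each direction in each main contrast and the 4 in each other contrast. They had an adjusted p under 0.05, a mean of at least 5 CPM in the higher group, every library of 1 side above every library of the other, and a symbol. The contrast of changes with age took 4 per direction with no overlap rule. All study regulators and limb identity genes, and up to 4 called members of each list with the largest change, were named as well. Mitochondrial rows and rows missing from dorsal E9 were named after their values were seen.

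The first set of alternatives held pseudocounts of 0.5 and 2 CPM, no filter and a filter at 5 CPM, median-of-ratios scaling, quantile normalization, only the libraries of the groups compared, no mean-variance trend, robust moderation and replicate number as a block. It also held edgeR's quasi-likelihood test with TMM scaling and DESeq2 on recovered reads, the estimated correlation for lists, and each replicate left out in turn. A lone library left in its group was then assumed to vary like the others. Alternatives added after seeing the data left out the rows missing from dorsal E9 with Z-listed genes, the dorsal E9 libraries, or the thigh E9 libraries. On simulated data limma recovered 73.1%, 44.8% and 57.6% of genes changed 2-fold in the 3 main contrasts in order. The shares were 97%, 95.5% and 96.9% with 4-fold changes, and 24.2%, 13.4% and 9.2% with 1.5-fold changes. False calls made up 1.5%, 5.6% and 7% of the calls at an adjusted p under 0.05. Simulated genes of a like level shared 1 spread, the same in every group, which the data need not have. Recovery in the data may therefore be lower. The versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.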

Results

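Transcripts were measured by RNA sequencing in skin of White Leghorn chicken embryos, taken from regions that form feathers and from a region that forms scales. The feather-forming regions were dorsal skin at embryonic days 7 and 9 (E7 and E9), thigh skin at E9 and wing skin at E9, and the scale-forming region was skin of the tarsometatarsus, the lower leg, at E9 and E11. Each of these 6 groups had 2 libraries, 12 in all, from Hamburger and Hamilton stages 31, 35 and 37 at E7, E9 and E11. Sample titles name dermis and tissue labels name skin. Epidermal transcripts were present: COL17A1, a collagen of basal keratinocytes, stood at 74.2 ± 43.1 CPM (SD, n = 2) in scale E9, CPM being read counts scaled to library size. How much epidermis each library held is not given. Differences in epidermal genes therefore cannot be told apart from differences in that share. The libraries held 13164609 to 20641980 reads on the rows of the table. Values per group are mean CPM ± SD over 2 libraries, and fold changes are log2 values with their standard error.

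The first pair of principal components carried 26.1% and 24.8% of the variance. Dorsal E9, wing E9, scale E9 and scale E11 each lay apart from the other groups on them, while thigh E9 replicate 1 lay nearer to dorsal E7 than to thigh replicate 2. Dorsal E9 lay at -51.7 and -48.6 on the first component and scale E9 at 31.3 and 37.9. Both dorsal E9 libraries lacked 26 rows that every other library had, among them HINTW and SPINW, genes of the female W chromosome. Those rows summed to 2.7 and 2.6 CPM in dorsal E9 and to between 399.3 and 1109.3 CPM in the other 10 libraries. Replicate 2 of thigh E9 stood apart as well: 12 mitochondrial transcripts made up 12.9% of its signal, against 3.24% to 4.75% in the other 11 libraries. The Spearman correlation across genes between the replicates was 0.970 in the thigh and 0.987 to 0.996 in the other 5 groups.

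**Figure D1:**
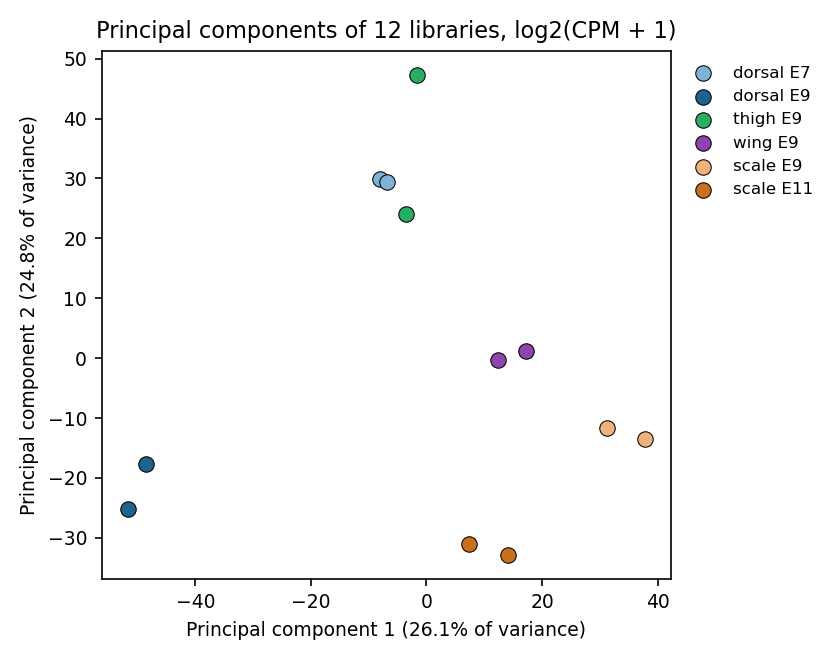
Principal components of log2(CPM + 1) values of the 12 libraries, each point a library and each colour a group. Both dorsal E9 libraries lie at the negative end of the first component (-51.7 and -48.6) and both scale E9 libraries at the positive end (31.3 and 37.9).

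The first comparison asked which genes differ between scale-forming and feather-forming skin at the same age. Scale E9 was set against the mean of dorsal, thigh and wing E9. All scale skin came from the tarsometatarsus, so differences of appendage and of body site cannot be told apart. Scales also start to form later than back feathers, so differences in the timing of appendage formation cannot be told apart from these either. The zinc-finger gene ZIC1 (ENSGALT00000040476.2) gave the largest difference. It stood at 122 ± 24.8 CPM in dorsal, 17.2 ± 4.41 in thigh and 369 ± 35.9 in wing skin, against 0.63 ± 0.01 in scale skin (log2 fold change -5.84 ± 0.17, adjusted p 6.04e-10). The hindlimb gene TBX4 (ENSGALT00000008476.4) was the largest in the other direction, at 167 ± 26.3 CPM in scale skin against 35.5 ± 14.4 in thigh, 2.66 ± 0.74 in dorsal and 2.71 ± 0.20 in wing skin (4.43 ± 0.21, adjusted p 4.75e-08). SOX18 (ENSGALT00000045917.1), a transcription factor of endothelium and dermis, was lower in scale skin, at 14.7 ± 6.25 CPM against 357 ± 17.0, 48.4 ± 1.87 and 84.9 ± 3.64 in dorsal, thigh and wing (-2.93 ± 0.18, adjusted p 3.69e-07). In all, 2042 genes passed an adjusted p of 0.05, of which 954 were higher and 1088 lower in scale skin, and 363 and 494 of these differed by at least 2-fold.

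Genes with the next largest differences included transcription factors and genes of other kinds. Higher in scale E9 were Pax-9 (3.92 ± 0.18), PRDM6 (3.47 ± 0.27), PRDM12 (2.88 ± 0.16), the hindlimb gene PITX1 (2.75 ± 0.19) and LHX9 (2.72 ± 0.38). So were NPTX2 (3.50 ± 0.18), IGSF10 (3.23 ± 0.17), STK32A (3.18 ± 0.20), ADARB2 (3.11 ± 0.21), TMEM132E (3.0 ± 0.25) and the desmosome gene PKP2 (2.75 ± 0.18). NPTX2 reached 255 ± 10.7 CPM in scale E9, against 10.6 ± 0.29 in dorsal, 11.5 ± 1.2 in thigh and 81.2 ± 26.7 in wing skin. Lower were SIM1 (-3.25 ± 0.18), TRPS1 (-3.08 ± 0.25) and OSR1 (-3.02 ± 0.17). The growth factor IGF2 (-3.32 ± 0.15) was lower too, as were PXDNL, PDE1A, MASP1 and DCLK1 (-3.19 to -2.90). All genes named in this and the preceding paragraph by the naming rule kept their call without either dorsal or thigh libraries and without any single library. The count itself became 1579 without the dorsal E9 libraries and 2656 without the thigh E9 libraries. It was 3758 without thigh replicate 1, 1283 without scale E9 replicate 1 and 1026 without scale E9 replicate 2.

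Of the 5 regulators known from the study, SOX2 is not among the measured genes and is not analysed here. Of the other 4, none was higher and 3 were lower in scale E9 (3 adjusted over the list alone; camera adjusted p 0.000272, and adjusted p = 0.0813 with an estimated correlation). A list taken from the study is not independent evidence of its direction. SPRY2, an inhibitor of FGF receptor signalling, differed by -0.62 ± 0.12 from the mean of the 3 regions, but by -0.34 ± 0.14 from wing skin (adjusted p 0.182). GRHL1, a factor of epidermal differentiation, differed by 0.36 ± 0.24 (adjusted p 0.372). All 3 limb identity genes were called, PITX1 and TBX4 higher and TBX5 lower (2 and 1 adjusted over the list alone; camera adjusted p 0.0562). TBX5, the forelimb gene, stood at 33.5 ± 7.83 CPM in wing and at most 0.53 ± 0.06 in every other group.

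**Figure D2:**
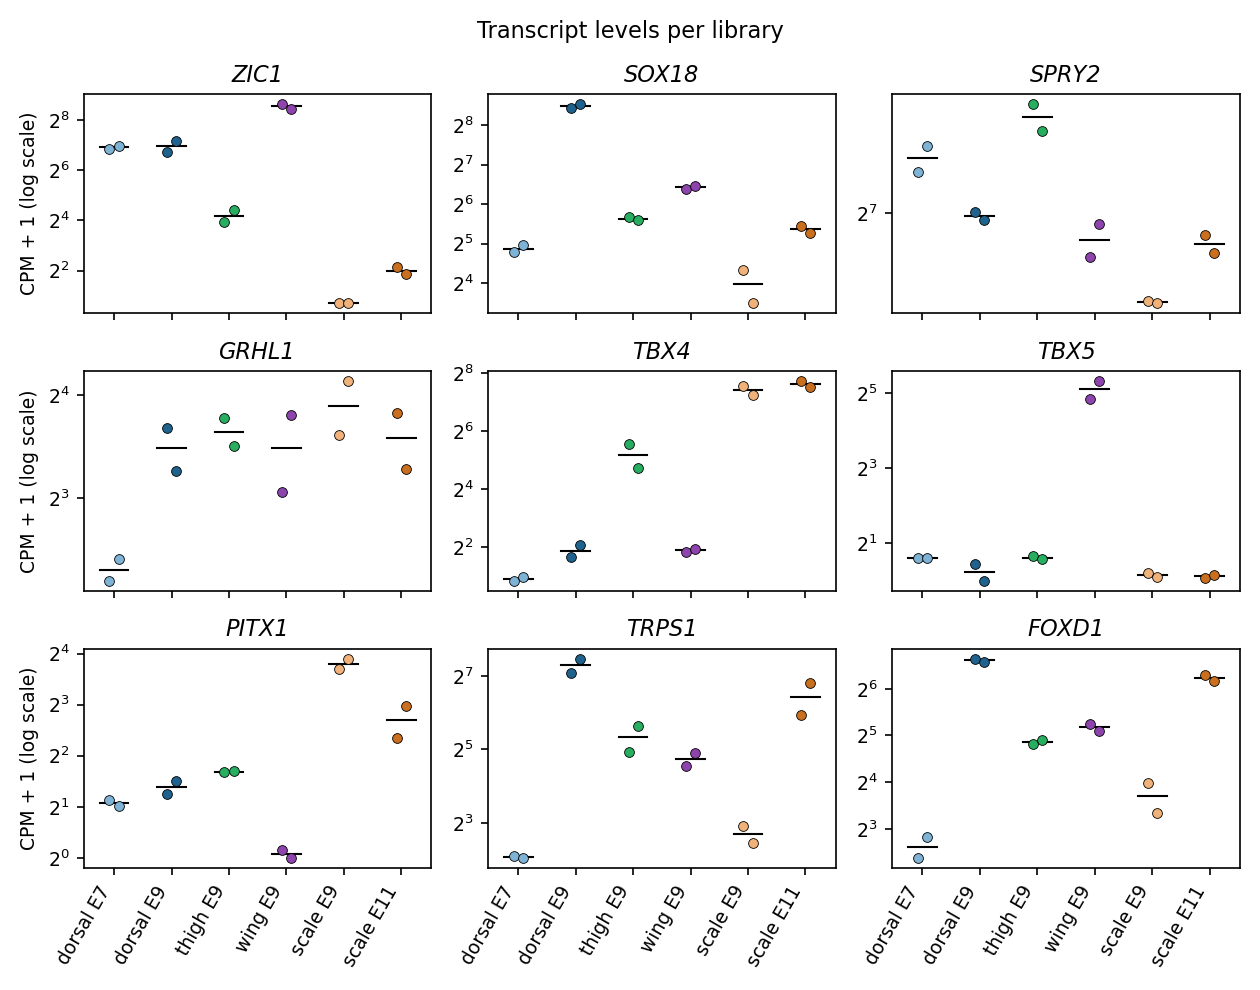
CPM + 1 on a log axis of regulators, limb genes, TRPS1 and FOXD1, with a point for each of the 12 libraries and a line at each group's mean. ZIC1 stood at 0.63 CPM in scale E9 and between 17.2 and 369 CPM in the E9 feather groups, while TBX4 stood at 167 CPM in scale E9 and at most 35.5 CPM in them.

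Markers of blood vessels were lower in scale E9: 20 of 24 endothelial markers were lower and 1 higher (21 and 1 adjusted over the list alone; camera adjusted p 1.42e-11, and adjusted p = 0.321 with an estimated correlation). TEK (-2.06 ± 0.23) and MMRN2 (-1.61 ± 0.19) were among the lower ones, and PROX1 of lymphatic endothelium was the higher one (1.68 ± 0.23). Many endothelial markers were also lower in thigh and in wing than in dorsal E9, so dorsal E9 carries part of the difference. SOX18 belongs to this list, to the study regulators and to the dermal condensation list. Smooth muscle and pericyte markers were lower for 9 of 13 (9 adjusted over the list alone; camera adjusted p 1.79e-06, and adjusted p = 0.0813 with an estimated correlation), led by MYH11 (-1.91 ± 0.19). Without the dorsal E9 libraries TAGLN (-0.50, adjusted p 0.303), ACTG2 (-0.89, adjusted p 0.0631) and RGS5 (-0.48, adjusted p 0.0853) lost the call. Keratinocyte markers were higher for 12 of 36 and lower for 1 (17 and 1 adjusted over the list alone; camera adjusted p 1.79e-06, and adjusted p = 0.471 with an estimated correlation). COL17A1 (2.06 ± 0.41) and CDH1 (1.74 ± 0.43) led them, and the lower member was TFAP2C (-1.78 ± 0.19). Without scale E9 replicate 2 the differences of COL17A1 (1.44, adjusted p 0.108) and CDH1 (1.30, adjusted p 0.217) no longer passed.

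Signalling genes went both ways. NOTCH pathway genes were lower for 5 of 16 and higher for none (5 and 0 adjusted over the list alone; camera adjusted p 0.00543, and adjusted p = 0.416 with an estimated correlation). The ligands DLL1 (-2.25 ± 0.17) and JAG1 (-1.99 ± 0.16) led these. Of 12 hedgehog pathway genes 3 were lower and 1 higher (5 and 1 adjusted over the list alone; camera adjusted p 0.0623), and the receptor PTCH1, itself a target of the pathway, differed by -1.28 ± 0.15. HHIP lost the call without the dorsal E9 libraries (-0.52, adjusted p 0.185) and without scale E9 replicate 2 (-0.78, adjusted p 0.0641). The higher gene, BOC (0.56), lost it without either replicate of dorsal, wing or scale E9 (0.40, adjusted p 0.339, without scale E9 replicate 1) and with only the libraries compared. WNT pathway genes were higher for 15 and lower for 10 of 44 (18 and 11 adjusted over the list alone; camera adjusted p 0.113), with the inhibitor SFRP4 at 2.21 ± 0.17 and the ligand WNT16 at -2.09 ± 0.33. FGF pathway genes were higher for 5 and lower for 7 of 25 (5 and 7 adjusted over the list alone; camera adjusted p 0.383), the lower ones including FGF18 (-2.0 ± 0.22), FGF16 (-1.79 ± 0.17) and FGF7 (-1.69 ± 0.19). BMP and TGF-beta genes were higher for 5 and lower for 10 of 34 (6 and 10 adjusted over the list alone; camera adjusted p 0.245), with FST, which binds activins, at -2.12 ± 0.19. Retinoic acid genes were higher for 3 and lower for 3 of 15 (3 and 3 adjusted over the list alone; camera adjusted p 0.383), from CRABP-I (2.43 ± 0.19) to STRA6 (-2.01 ± 0.24). EDA pathway genes were higher for 2 and lower for 1 of 6 (2 and 2 adjusted over the list alone; camera adjusted p 0.395), with NFKBIA at 1.75 ± 0.20. The other 2 calls ended without the dorsal E9 libraries, that of TNFRSF19 at 0.49 (adjusted p 0.118) and that of the lower gene, Edar, at -0.04 (adjusted p 0.949). Edar also missed the threshold with edgeR, with only the libraries compared, and without dorsal E9 replicate 2, wing replicate 2 or scale E9 replicate 1 (-0.38, adjusted p 0.558), and TNFRSF19 without scale E9 replicate 2 (0.71, adjusted p 0.104).

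Connective tissue genes also split. Dermal matrix genes were higher for 6 and lower for 10 of 40 (12 and 14 adjusted over the list alone; camera adjusted p 0.245), with ASPN (-2.71 ± 0.19), DPT (-2.12 ± 0.22) and FBLN1 (-2.10 ± 0.14) the lowest. Cartilage markers were higher for 5 and lower for 5 of 20 (5 and 5 adjusted over the list alone; camera adjusted p 0.840): COL9A2 (2.35 ± 0.25) and COL2A1 (2.03 ± 0.25) were higher, and MATN4 (-1.95 ± 0.24) and SOX6 (-1.77 ± 0.21) lower. COL2A1 reached 935 ± 98.5 CPM in scale E9. Tendon markers were higher for 2 and lower for 3 of 12 (4 and 5 adjusted over the list alone; camera adjusted p 0.245), TNMD being higher (1.43 ± 0.22) and THBS4 lower (-1.79 ± 0.14). Dermal condensation genes were higher for 3 and lower for 5 of 18 (4 and 5 adjusted over the list alone; camera adjusted p 0.257), and dorsal and trunk dermis genes higher for 7 and lower for 7 of 22 (8 and 9 adjusted over the list alone; camera adjusted p 0.771). No list call in this comparison held with an estimated correlation.

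**Figure D3:**
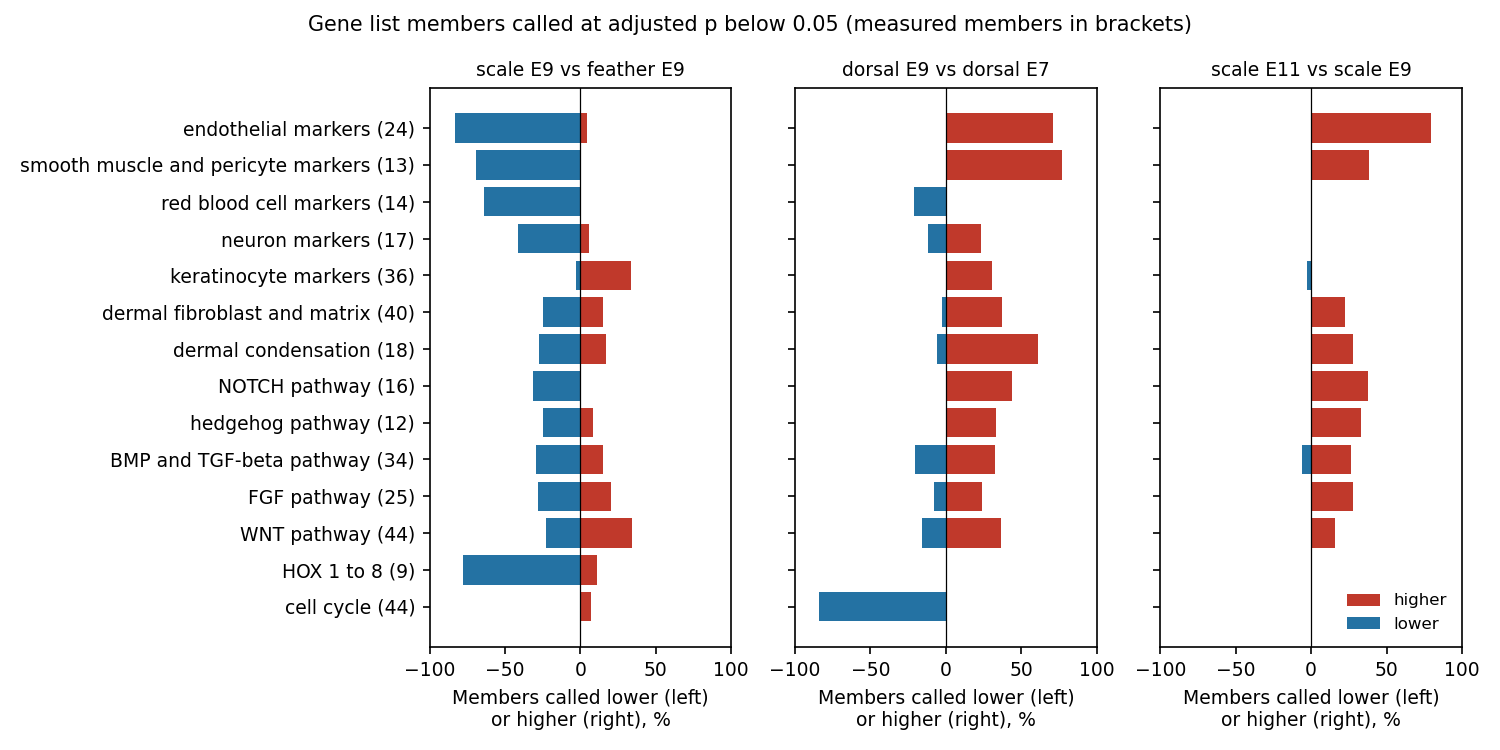
Percent of the members of each gene list called lower (bars to the left) and higher (bars to the right) in the 3 main comparisons, with the number of measured members in brackets. Endothelial markers had 20 of 24 members lower in scale E9 than in feather skin, 17 higher at E9 than E7 in dorsal skin, and 19 higher at E11 than E9 in scale skin.

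Scale E9 was also set against each feather region alone. Against dorsal E9, 2676 genes were called (1133 higher, 1543 lower; 42.3% higher, and 49.4% after quantile normalization). Asip (5.71 ± 0.20), a pigment-switching signal, was among the higher and CALB2 (-6.02 ± 0.32), MYOCD (-5.26 ± 0.27) and HOXB5 (-4.92 ± 0.25) were among the lower. HNRPK (6.44 ± 0.30) and HINTW (5.94 ± 0.44) ranked above Asip, and all 26 rows missing from dorsal E9 were called. Against thigh E9, 2995 genes were called (1438 higher, 1557 lower), including PRDM6 (4.78 ± 0.33), IGSF10 (4.50 ± 0.21), Six2 (3.91 ± 0.22), SIM1 (-4.30 ± 0.22) and ENPP3 (-4.09 ± 0.32). Against wing E9, 1092 genes were called (585 higher, 507 lower), including HOXC10 (4.69 ± 0.22), TBX5 (-4.95 ± 0.22) and PLSCR5 (-4.28 ± 0.21). The count against dorsal skin fell to 1757 without dorsal E9 replicate 1. That against thigh skin was 5541 without thigh replicate 1 and 1382 without scale E9 replicate 2, and that against wing skin was 500, 671 and 629 without wing replicate 1, wing replicate 2 and scale E9 replicate 1.

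In all, 404 genes were called in 1 direction against each of the 3 feather regions, 210 higher and 194 lower in scale E9, against 6.3 and 8.1 for independent lists. Body site and the timing of appendage formation stay confounded with appendage in this set too. The same scale libraries entered each of the 3 tests. They were shared in the same way in 20 simulated draws that hold no effects. In these a mean of 41.5 genes passed at an unadjusted p under 0.05 in all 3 tests, against 832 in the data. Limma called 0 genes there, but the adjustment of p-values makes that nearly certain where no gene has an effect. ZIC1 (-6.23, -3.46 and -7.83 against dorsal, thigh and wing), SOX18 (-4.57, -1.71 and -2.51) and TBX4 (5.53, 2.26 and 5.50, all with standard errors of 0.21 to 0.26) were in this set. The number was 618 without thigh replicate 1, 247 and 267 without wing replicates 1 and 2, and 234 without scale E9 replicate 2. The simulated draws hold no effects and give every group the same spread. They do not settle how much of the excess over independent lists comes from the shared libraries.

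The second comparison asked what changes in dorsal skin between E7 and E9, the interval in which feather buds form. TRPS1, a transcription factor known from hair and skeletal development, rose from 3.22 ± 0.13 to 155 ± 30.1 CPM (5.20 ± 0.31, adjusted p 1.84e-07). MASP1, a protease gene of the complement system, rose from 2.49 ± 0.54 to 225 ± 42.7 CPM (6.01 ± 0.28, adjusted p 3.12e-08). MYOCD, a coactivator of smooth muscle genes, rose from 1.2 ± 0.47 to 57.8 ± 1.64 CPM (4.75 ± 0.27). TFAP2C rose from 3.98 ± 0.09 to 127 ± 15.7 (4.68 ± 0.23) and tenascin gene TNC from 28.5 ± 0.77 to 480 ± 37.7 (4.03 ± 0.29). SOX18 rose from 28.3 ± 2.47 to 357 ± 17.0 CPM (3.61 ± 0.22, adjusted p 2.38e-07). ZIC1 stood at 119 ± 7.11 and 122 ± 24.8 CPM (0.03 ± 0.21, adjusted p 0.938). ROBO3, an axon guidance receptor, fell from 151 ± 10.3 to 8.35 ± 0.54 CPM (-4.02 ± 0.25). The proteoglycan gene PODN fell from 572 ± 59.1 to 43.8 ± 10.4 (-3.69 ± 0.17) and the steroid reductase gene AKR1D1 from 664 ± 68.1 to 42.8 ± 8.80 (-3.93 ± 0.24). Other genes that rose were ADAMTS17 (4.70), STOM (4.44), PXDNL (4.38), SPON2 (4.25), TAGLN (4.02) and FOXD1 (4.02). Others that fell were FRK (-4.70), SCN3A (-4.14), LIX1 (-4.01) and VWA3B (-3.80). The rule also named HNRPK (-6.20), HINTW (-5.77), RDM1 (-4.43), SPINW (-4.25) and CHDZ (-3.83), which are among the rows missing from dorsal E9.

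In all, 2471 genes were called, 1494 higher and 977 lower at E9, so that 60.5% were higher, 51.1% after quantile normalization, and 57.6% to 60.9% with median-of-ratios scaling, edgeR and DESeq2. Of the higher and lower genes, 891 and 410 differed by 2-fold or more; 26 were the rows missing from dorsal E9. The count was 1303 without E7 replicate 1, 1428 without E7 replicate 2, 1374 without E9 replicate 1, and 4405 with only the 4 libraries of these groups. GRHL1 rose by 1.17 ± 0.29, a call that ended without E7 replicate 1 (1.06, adjusted p 0.101) and without E9 replicate 1 (0.96, adjusted p 0.118), and SPRY2 differed by -0.32 ± 0.14 (adjusted p 0.142). Of the 4 study regulators 2 rose (2 adjusted over the list alone; camera adjusted p 0.188).

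Dermal condensation genes rose with age in dorsal skin, 11 of 18 being higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p 6.04e-07, and adjusted p = 0.0312 with an estimated correlation, so that the call held). FOXD1 (4.02 ± 0.22), TNC, SOX18 and PTCH1 (2.62 ± 0.19) were among them. Smooth muscle and pericyte markers rose for 10 of 13 (10 adjusted over the list alone; camera adjusted p 1.31e-09, and adjusted p = 0.0312 with an estimated correlation, so that this call held too), led by TAGLN (4.02 ± 0.39), MYH11 (3.87 ± 0.23) and RGS5 (3.30 ± 0.18). Endothelial markers rose for 17 of 24 (17 adjusted over the list alone; camera adjusted p 3.15e-07, and adjusted p = 0.366 with an estimated correlation), EGFL7 by 1.61 ± 0.20. Cell cycle genes moved the other way: 37 of 44 were lower at E9 and none higher (41 and 0 adjusted over the list alone), with a median of -0.87 (camera adjusted p 1.74e-19, and adjusted p = 0.103 with an estimated correlation). PLK1 stood at 271 ± 7.81 CPM at E7 and 125 ± 12.6 at E9.

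Among pathways in dorsal skin, NOTCH genes rose for 7 of 16 (8 adjusted over the list alone; camera adjusted p 3.45e-05, and adjusted p = 0.170 with an estimated correlation), JAG1 by 3.91 ± 0.19 and DLL1 by 3.0 ± 0.21. Hedgehog genes rose for 4 of 12 (6 adjusted over the list alone; camera adjusted p 0.0130, and adjusted p = 0.402 with an estimated correlation); the ligand SHH went from 0.12 ± 0.16 to 3.07 ± 0.42 CPM. BMP and TGF-beta genes were higher for 11 and lower for 7 of 34 (13 and 7 adjusted over the list alone; camera adjusted p 0.0147, and adjusted p = 0.353 with an estimated correlation), with BMP6 at 3.98 ± 0.16 and BMPER at 3.94 ± 0.17. WNT genes were higher for 16 and lower for 7 of 44 (17 and 7 adjusted over the list alone; camera adjusted p 0.176), from SOSTDC1 (3.15 ± 0.36) to SP5 (-3.07 ± 0.32). FGF genes were higher for 6 and lower for 2 of 25 (7 and 3 adjusted over the list alone; camera adjusted p 0.188), FGF7 rising by 2.25 ± 0.23. The EDA list had 1 gene higher and 1 lower of 6 (2 and 1 adjusted over the list alone; camera adjusted p 0.460), and its receptor Edar, of the placode epithelium, went from 5.36 ± 0.71 to 65.9 ± 6.07 CPM. Retinoic acid genes were higher for 4 and lower for 1 of 15 (5 and 1 adjusted over the list alone; camera adjusted p 0.416), the degrading enzyme CYP26B1 by 3.0 ± 0.19. RDH10 lost the call without any single library of the 4 (adjusted p 0.0852 to 0.135), and ALDH6 without dorsal E9 replicate 1 (adjusted p 0.0514). Keratinocyte markers rose for 11 of 36 (13 adjusted over the list alone; camera adjusted p 0.000383, and adjusted p = 0.641 with an estimated correlation). Matrix genes rose for 15 of 40 with 1 lower (16 and 1 adjusted over the list alone; camera adjusted p 0.000149, and adjusted p = 0.103 with an estimated correlation), FBLN2 by 2.70 ± 0.17. The dorsal E9 libraries, which lack the 26 rows named above, form 1 side of each of these tests.

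The third comparison asked what changes in scale-forming skin between E9 and E11. TRPS1 rose here too, from 5.51 ± 1.51 to 85.4 ± 36.1 CPM (3.68 ± 0.31, adjusted p 4.32e-05), and C1QTNF8 rose from 0.16 ± 0.06 to 21.3 ± 9.48 (4.19 ± 0.32). PHGDH, the first enzyme of serine synthesis from glucose, rose from 47.6 ± 19.5 to 340 ± 72.5 CPM (2.85 ± 0.26) and NDNF from 67.5 ± 20.5 to 455 ± 42.9 (2.77 ± 0.21). Other genes that rose included SS1R (3.60), ANO2 (3.65), the water channel gene AQP3 (3.23), PXDNL (3.17), TRPC7 (3.05), SYT10 (3.04) and CPXM2 (2.86). FOS rose by 3.18 ± 0.55, but by 2.91 with an adjusted p of 0.069 without scale E9 replicate 2. The largest falls were those of LHCGR (-2.31 ± 0.25), LRFN5 (-2.21 ± 0.21, from 75.1 ± 5.69 to 15.7 ± 4.46 CPM), SLC38A4 (-2.18), HSD17B2 (-2.06), DMRT2 (-2.05), B3GNT7 (-2.01), CUX2 (-1.98) and PRDM12 (-1.90 ± 0.20). SOX18 rose by 1.45 ± 0.22 and ZIC1 by 1.28 ± 0.21, from 0.63 ± 0.01 to 2.99 ± 0.57 CPM, which made 2 of the 4 study regulators (2 adjusted over the list alone; camera adjusted p 0.00974, and adjusted p = 0.116 with an estimated correlation). PITX1 fell by 1.14 ± 0.23, a call that ended without scale E9 replicate 2 (-1.04, adjusted p 0.103), without E11 replicate 1 (-0.84, adjusted p 0.0942) and with edgeR (adjusted p 0.0526).

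In all, 716 genes were called, 537 higher and 179 lower at E11, so that 75% were higher (64.5% after quantile normalization). The count was 207 without scale E9 replicate 2, 434 without E11 replicate 1 and 205 without E11 replicate 2. Endothelial markers rose for 19 of 24 (19 adjusted over the list alone), with a median of 1.41 (camera adjusted p 2.14e-19, and adjusted p = 0.116 with an estimated correlation), APLNR by 2.06 ± 0.27 and TEK by 1.97 ± 0.28. Dermal matrix genes rose for 9 of 40 (14 higher and 1 lower adjusted over the list alone; camera adjusted p 1.22e-06, and adjusted p = 0.0715 with an estimated correlation), COL3A1 from 1100 ± 101 to 3006 ± 144 CPM. NOTCH genes rose for 6 of 16 (7 adjusted over the list alone; camera adjusted p 1.16e-05, and adjusted p = 0.116 with an estimated correlation). Dermal condensation genes rose for 5 of 18 (9 adjusted over the list alone; camera adjusted p 8.75e-06, and adjusted p = 0.0699 with an estimated correlation). FGF genes rose for 7 of 25 (7 higher and 1 lower adjusted over the list alone; camera adjusted p 0.00455, and adjusted p = 0.351 with an estimated correlation), among them FGFRL1 (2.01 ± 0.26) and FGF18 (1.84 ± 0.27). BMP and TGF-beta genes were higher for 9 and lower for 2 of 34 (9 and 5 adjusted over the list alone; camera adjusted p 0.0152, and adjusted p = 0.348 with an estimated correlation), TGFBI at 2.51 ± 0.25. Smooth muscle and pericyte markers rose for 5 of 13 (7 adjusted over the list alone; camera adjusted p 5.12e-05, and adjusted p = 0.116 with an estimated correlation), RGS5 by 1.5 ± 0.18. No list call in this comparison held with an estimated correlation.

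Keratinocyte markers had a median of -0.67 at E11 against E9, with 1 of 36 lower and none higher (1 and 0 adjusted over the list alone; camera adjusted p 5.42e-07, and adjusted p = 0.429 with an estimated correlation). Cell cycle genes had a median of -0.34, and limma called 0 of 44 (0 adjusted over the list alone). The list as a whole was lower than other genes (camera adjusted p 2.14e-10, and adjusted p = 0.126 with an estimated correlation). Hedgehog genes rose for 4 of 12 (4 adjusted over the list alone; camera adjusted p 0.0204, and adjusted p = 0.429 with an estimated correlation), with PTCH1 at 1.22 ± 0.19. Without scale E9 replicate 2 the calls of HHIP (1.04, adjusted p 0.0787) and GLI1 (0.71, adjusted p 0.261) ended. WNT genes rose for 7 of 44 (8 higher and 1 lower adjusted over the list alone; camera adjusted p 0.346), FRZB by 1.58 ± 0.19. Tendon markers were higher for 4 and lower for 1 of 12 (4 and 1 adjusted over the list alone; camera adjusted p 0.0114, and adjusted p = 0.123 with an estimated correlation), MKX going from 4.73 ± 0.73 to 31.6 ± 19.1 CPM.

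The changes with age in dorsal and in scale skin shared many genes. Of the genes that rose in dorsal skin, 366 also rose in scale skin, against 65.3 for independent lists (Fisher's exact test, p 2.68e-217), and 97 fell in both, against 14.2 (p 1.38e-59). TRPS1, PXDNL, FOXD1, BMP6, JAG1 and SOX18 rose in both, and AKR1D1 fell in both. Of the genes that rose in dorsal skin 13 fell in scale skin (21.8 for independent lists, p 0.0491), and of those that fell 11 rose (42.7, p 2.64e-09). Across all genes the changes correlated with a Pearson r of 0.496 and a Spearman rho of 0.466, and genes are not independent replicates. The pair of contrasts shares no library. Both use the same variance per gene from all 12 libraries, however, so their calls are not independent.

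The size of the change with age was compared directly between scale and dorsal skin. It differed for 612 genes, 243 of them with a more positive change in scale skin and 369 with a more negative one (39.7% positive, and 44.3% after quantile normalization). TFAP2C (-4.93 ± 0.32), MYOCD (-4.45 ± 0.38) and MYH11 (-3.69 ± 0.32) were among the most negative differences. In scale skin at E9 and E11 MYH11 stood at 8.82 ± 1.32 and 10.2 ± 2.09 CPM. SOX18 rose less in scale than in dorsal skin (-2.16 ± 0.31, adjusted p 0.00126). ROBO3 differed the other way (4.33 ± 0.36): it fell in dorsal skin from 151 ± 10.3 CPM, and stood at 3.04 ± 1.66 and 3.78 ± 0.38 CPM in scale skin. The rows HNRPK (5.77), HINTW (5.14) and RDM1 (4.88) are missing from dorsal E9. Smooth muscle and pericyte genes differed for 6 of 13, all lower (7 adjusted over the list alone; camera adjusted p 1.01e-06, and adjusted p = 0.0857 with an estimated correlation). Dermal condensation genes differed for 6 of 18, all lower (7 adjusted over the list alone; camera adjusted p 8.24e-05, and adjusted p = 0.0857 with an estimated correlation). Keratinocyte markers differed for 4 of 36, all lower (21 adjusted over the list alone; camera adjusted p 7.64e-14, and adjusted p = 0.531 with an estimated correlation). The count was 264 and 300 without E7 replicates 1 and 2, 343 without dorsal E9 replicate 1, 331 without scale E9 replicate 2, and 373 and 388 without E11 replicates 1 and 2. The E7-to-E9 and E9-to-E11 intervals also differ in age.

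**Figure D4:**
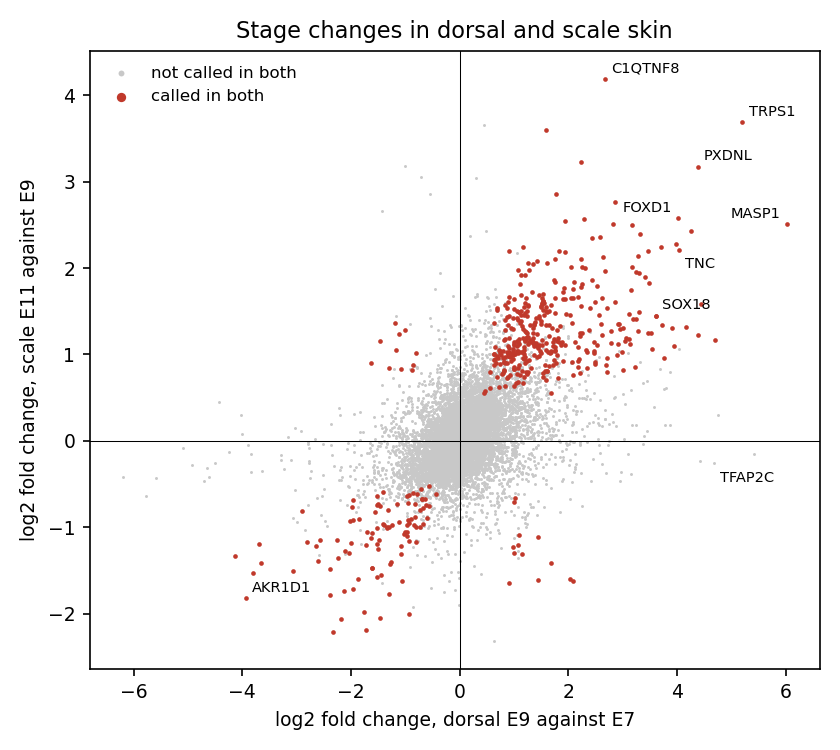
Log2 fold change of each gene with age in dorsal skin (E9 against E7, horizontal) and in scale skin (E11 against E9, vertical), each point a gene, and red those called in both. Of these 366 rose in both and 97 fell in both, while TFAP2C rose by 4.68 in dorsal skin and changed by -0.25 in scale skin.

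The feather regions at E9 also differed from each other, which asked what separates skin that forms the same appendage at different sites. HOX genes were prominent between wing and dorsal skin: HOXD12 stood at 140 ± 12.3 CPM in wing and 0.03 ± 0.04 in dorsal skin (7.11 ± 0.32), and HOXC10 at 1.39 ± 0.15 and 277 ± 18.8 (-6.86 ± 0.22). HOXD11 (5.58 ± 0.23) and SALL1 (5.55 ± 0.22) were also higher in wing, and HOXB5 (-4.59), HOXB6 (-4.37) and HOXC6 (-4.25) lower. Of 9 measured anterior HOX genes 5 were lower and 1 higher in wing than in dorsal skin (5 and 2 adjusted over the list alone; camera adjusted p 0.00278, and adjusted p = 0.322 with an estimated correlation). Wing against thigh gave HOXD12 (6.59), HOXD11 (5.75) and HOXD13 (4.76) higher and HOXC10 (-6.12), PAPPA2 (-5.14), COL20A1 (-4.57) and OMD (-4.29) lower. Thigh against dorsal gave Asip (5.66 ± 0.20) and OMD (5.41 ± 0.24) higher and CALB2 (-6.17), TNC (-4.63) and EP3 (-4.26) lower. Against the mean of the feather regions, scale E9 was lower for 7 and higher for 1 of 9 anterior HOX genes (7 and 1 adjusted over the list alone; camera adjusted p 0.000194, and adjusted p = 0.321 with an estimated correlation). Without the dorsal E9 libraries, however, the 4 lower genes with the largest differences all lost the call: HOXB5 (-0.52, adjusted p 0.163), HOXB4 (-0.51, adjusted p 0.0996), HOXB3 (-0.29, adjusted p 0.484) and HOXB6 (0.005, adjusted p 0.990). HOXB3 lost it without scale E9 replicate 2 as well (-0.85, adjusted p 0.0699). Of 10 posterior HOX genes 2 were higher and 3 lower in scale E9 (2 and 3 adjusted over the list alone; camera adjusted p 0.637), the lower ones including HOXD10 (-1.47 ± 0.21) and HOXD9 (-1.38 ± 0.17). The higher ones, HOXD12 and HOXD13, lost the call without the dorsal E9 libraries (0.22, adjusted p 0.639, and 0.33, adjusted p 0.308) and without the thigh E9 libraries (0.48, adjusted p 0.158, and 0.34, adjusted p 0.249). HOXD12 stood at 15.9 CPM in scale E9, far below wing skin.

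Dorsal E9 also stood apart in cell cycle genes, with 35 of 44 higher and 1 lower in thigh (36 and 1 adjusted over the list alone; camera adjusted p 5.05e-15, and adjusted p = 0.238 with an estimated correlation). In wing 30 were higher than in dorsal skin (40 adjusted over the list alone; camera adjusted p 2.04e-16, and adjusted p = 0.181 with an estimated correlation). Endothelial markers were lower than in dorsal skin for 13 of 24 in thigh (16 adjusted over the list alone; camera adjusted p 6.87e-06, and adjusted p = 0.532 with an estimated correlation). In wing this held for 22 (23 adjusted over the list alone; camera adjusted p 2.86e-12, and adjusted p = 0.226 with an estimated correlation). Counts were 3681 for thigh against dorsal (1658 higher, 2023 lower), 2469 for wing against dorsal (936 and 1533) and 2561 for wing against thigh (1136 and 1425). The share of higher genes moved from 45% to 50.1%, from 37.9% to 47.8% and from 44.4% to 48% after quantile normalization. With median-of-ratios scaling, edgeR and DESeq2 it was 48%, 47.3% and 51.3% for thigh against dorsal, 39.7%, 38.2% and 41.2% for wing against dorsal, and 43.1%, 42% and 41.2% for wing against thigh. Thigh against dorsal gave 5905 without thigh replicate 1 and 1717 without dorsal replicate 1, and 1480 with only its 4 libraries. Wing against dorsal gave 1313 and 1643 without dorsal replicates 1 and 2, 1108 and 1634 without wing replicates 1 and 2, and 4128 with only its 4 libraries. Wing against thigh gave 4697 without thigh replicate 1, 882 and 1460 without wing replicates 1 and 2, and 900 with only its 4 libraries.

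**Figure D5:**
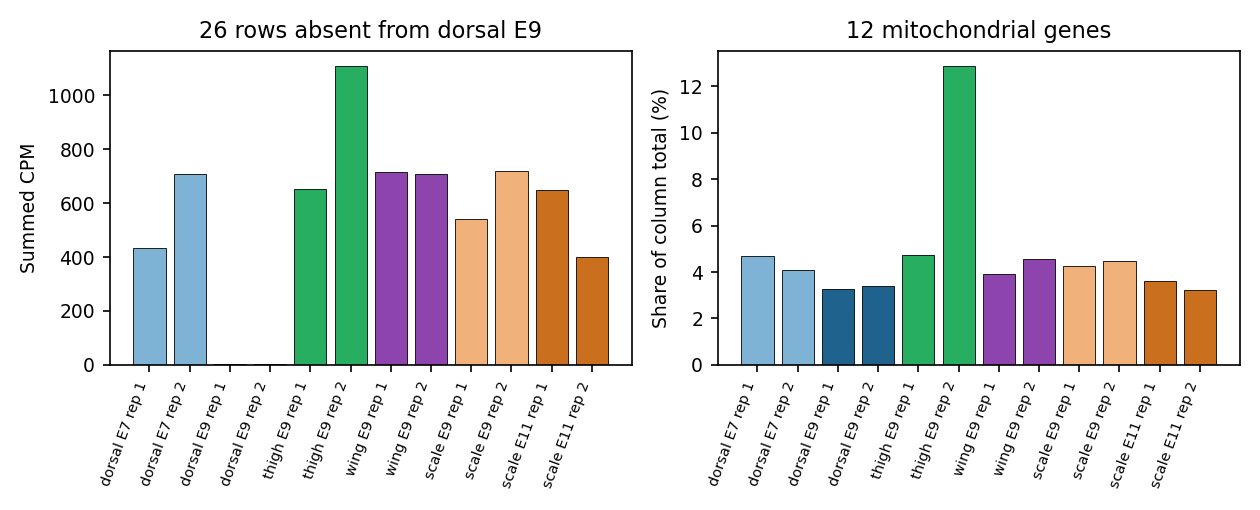
Per library, the summed CPM of the 26 rows missing from dorsal E9 and the percent of signal on 12 mitochondrial transcripts. Dorsal E9 libraries hold 2.7 and 2.6 CPM of the former, and replicate 2 of thigh E9 holds 12.9% of the latter.

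Scale skin was compared with dorsal skin across ages as well. Scale E9 against dorsal E7 gave 1631 genes (923 higher, 708 lower). TBX4 (6.47 ± 0.26), IGSF10 (5.63 ± 0.21), NPTX2 (5.37 ± 0.23) and Pax-9 (4.97 ± 0.22) were higher, and ZIC1 (-6.19 ± 0.21), HOXB5 (-5.34 ± 0.25), ROBO3 (-5.29 ± 0.25) and the embryonic globin gene HBG1 (-5.03 ± 0.39) were lower. Keratinocyte markers were higher for 27 of 36 (31 adjusted over the list alone; camera adjusted p 9.51e-18, and adjusted p = 0.303 with an estimated correlation). Scale E11 against dorsal E9 gave 1463 genes (715 higher, 748 lower), with TBX4 (5.75 ± 0.26) and Asip (5.14 ± 0.20) higher, CALB2 (-5.54 ± 0.32), MYOCD (-4.96 ± 0.27), ZIC1 (-4.94 ± 0.21), HOXC6 (-4.31 ± 0.29) and SOX18 (-3.12 ± 0.22) lower. HNRPK (6.02) and HINTW (5.30), of the rows missing from dorsal E9, were higher too. The count for scale E9 against dorsal E7 was 906 and 982 without E7 replicates 1 and 2 and 1042 without scale E9 replicate 2. That for scale E11 against dorsal E9 was 940 without dorsal E9 replicate 1 and 924 without E11 replicate 1.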

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

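All tests of the weighed patterns in this part were chosen after the missing rows and the level of SOX18 in dorsal E9 had been seen, and before their own outcomes were. The interaction tests between changes with age were planned, except for the count without sex-linked rows.

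The change with age differed between scale and dorsal skin for 612 genes by a direct test of the difference, and for 554 of the remaining genes once the rows missing from dorsal E9 and Z-listed genes were left out. The differences were 5.77 for HNRPK, 5.14 for HINTW and 4.88 for RDM1, all missing from dorsal E9. ROBO3 differed by 4.33, since it fell in dorsal skin from 151 CPM and stood at 3.04 CPM in scale E9. TFAP2C differed by -4.93, MYOCD by -4.45 and MYH11 by -3.69, and SOX18 by -2.16. ZIC1 differed by 1.25 (adjusted p 0.0293), but by 0.89 (adjusted p 0.11) with a pseudocount of 2 CPM. It also missed the threshold after quantile normalization (1.09), without E7 replicate 1 (1.31) or 2 (1.19), dorsal E9 replicate 1 (1.04), scale E9 replicate 1 (1.24) or 2 (1.26), and E11 replicate 1 (1.11). PITX1 differed by -1.45 (adjusted p 0.0211), and missed the threshold with edgeR (-1.80) and without E7 replicate 1 (-1.51) or 2 (-1.40), dorsal E9 replicate 2 (-1.32), scale E9 replicate 2 (-1.35) and E11 replicate 1 (-1.15).

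Both dorsal E9 libraries lacked 26 rows, which summed to 2.7 and 2.6 CPM against 399.3 to 1109.3 CPM elsewhere, and all W-linked genes measured were lower in dorsal E9 than in E7 (4 of 4, 4 adjusted over the list alone; camera adjusted p 7.69e-07, and adjusted p = 0.112 with an estimated correlation). An assignment of reads from W copies to other rows would leave most Z-linked genes in place. Genes of the Z list were higher in dorsal E9 than in the mean of the other 5 groups by a median of 0.21 relative to other genes (bootstrap 95% interval 0.14 to 0.24, 293 genes). The interval covers spread between genes, not between groups. Among groups that hold the missing rows, the list's median was -0.15 for scale E9 against thigh E9 and -0.13 for wing against thigh. It was -0.01 for scale E9 against wing E9 and 0 for scale E9 against dorsal E7. Against dorsal E9 it was -0.21 for scale E9, -0.2 for wing, -0.2 for scale E11 and -0.12 for thigh, and dorsal E9 against E7 gave 0.24. The interval lies above the limit set beforehand for such an assignment, which goes against it. Differences of like size between thigh and other groups that hold the rows leave it open nonetheless. The value goes with the explanation that the dorsal E9 embryos may all have been male, while other groups held female tissue. It does not settle this. The sex of the embryos is not given, and the placement of genes on Z came from general knowledge rather than from the table. In comparisons with dorsal E9, sex stays confounded with the group.

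SOX18 stood at 357 CPM in dorsal E9 and 28.3 CPM in dorsal E7, a rise of 3.61. A larger share of endothelial cells would raise the other endothelial markers by a like amount, yet their median rise was 0.98 (bootstrap 95% interval 0.68 to 1.17, 23 genes), below 1.81, which is 0.5 of the rise of SOX18. A larger endothelial share may account for part of the rise, but the interval argues against it as the cause of all of it. A rise within cells of the dermis, or in endothelium itself, was not tested.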

How the results depend on the processing

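The alternatives without dorsal E9 libraries, without thigh E9 libraries and without sex-linked rows were chosen after seeing the data; the others were planned. Of 5997 comparisons of a named gene with an alternative other than a left-out replicate, 5909 kept direction and call, 80 lost the call, 6 gained it and 2 reversed. HOXB6 (0.005) and SPINW (-0.49) reversed in scale E9 against feather E9 without the dorsal E9 libraries, which held their extreme values. Of 2316 comparisons with a replicate left out 2089 kept the call and 227 lost it, 64 of the 267 without scale E9 replicate 2 among them. With only the libraries of the groups compared, the count was 1275 for scale E9 against thigh E9, 1480 for thigh against dorsal and 900 for wing against thigh. It was 4405 for dorsal E9 against E7 and 4128 for wing against dorsal. Fewer libraries then set the variance, but the groups also differed in spread. The SD of the log2 difference between replicates was 0.536 in thigh E9 and 0.217 to 0.354 in the other groups. The main fit uses 1 variance per gene for all groups, so its counts against thigh skin may be too high. Counts without thigh replicate 1 rest on replicate 2, which held the excess of mitochondrial transcripts. Leaving out 1 replicate gave 1026 to 3758 genes for scale E9 against feather E9, 1757 to 2072, 1382 to 5541 and 500 to 730 against dorsal, thigh and wing, and 234 to 618 against all 3 in 1 direction. It gave 1303 to 1826 for dorsal E9 against E7, 205 to 530 for scale E11 against E9, 264 to 528 for the difference of these changes, 1717 to 5905 for thigh against dorsal, 1108 to 1643 for wing against dorsal, 882 to 4697 for wing against thigh, 906 to 1347 for scale E9 against dorsal E7 and 924 to 1033 for scale E11 against dorsal E9. The cause was not tested, but replicates of thigh E9 had the lowest Spearman correlation (0.970). With edgeR and DESeq2 scale E9 against feather E9 gave 1934 and 2242 genes, which held 92.1% and 94.7% of the calls, and with replicate number as a block 2160. No scaling moved the median of all genes by over 0.1. Sequencing depth limits genes under 1 CPM, and 2-fold changes were recovered for 44.8% to 73.1% of simulated genes.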

Other observations

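Tests in this part on mitochondrial transcripts, ribosomal protein genes and the lag of scale skin, and those of Spearman correlations and of counts without sex-linked rows, were chosen after the patterns had been seen; the gene lists were planned.

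Markers of blood, nerve and pigment cells were compared between regions and ages. Red blood cell markers were lower in scale E9 than in feather skin for 9 of 14 and higher for none (11 and 0 adjusted over the list alone; camera adjusted p 3.11e-06, and adjusted p = 0.416 with an estimated correlation). Without scale E9 replicate 2 HBG1 (-1.31, adjusted p 0.0664), HBE1 (-1.07, adjusted p 0.198) and TSPO2 (-1.23, adjusted p 0.163) lost the call, and without the dorsal E9 libraries HBE1 did (-1.33, adjusted p 0.0569). The globin gene HBE stood at 2.23 ± 0.76 CPM there, against 18.7 ± 1.23 in dorsal and 20.7 ± 1.49 in thigh skin, and at 9.02 ± 8.95 in wing skin, where the 2 libraries differed widely. In dorsal skin with age 3 of 14 fell, HBG1 by 2.93 ± 0.39 (3 adjusted over the list alone; camera adjusted p 0.935). The list's median was 0.43 there, against a test direction of down. In scale skin with age limma called 0 of them (6 higher adjusted over the list alone; camera adjusted p 0.000412, and adjusted p = 0.429 with an estimated correlation). Neuron markers were lower in scale E9 for 7 of 17 and higher for 1 (11 and 2 adjusted over the list alone; camera adjusted p 0.000481, and adjusted p = 0.0813 with an estimated correlation). UCH-L1 (-1.48 ± 0.16) and ELAVL4 (-1.26 ± 0.18) were among the lower ones. With age in dorsal skin 4 neuron markers rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p 0.405). The falling ones were GAP43 (-2.79 ± 0.39) and TUBB3 (-2.11 ± 0.37). In scale skin none was called with age (1 higher and 1 lower adjusted over the list alone; camera adjusted p 0.606). Melanocyte markers were higher for 1 and lower for 2 of 17 in scale E9 (1 and 2 adjusted over the list alone; camera adjusted p 0.113). Of the lower ones KIT lost the call without the dorsal E9 libraries (-0.44, adjusted p 0.221) and without scale E9 replicate 1, and RAB38 without scale E9 replicate 1 (-0.69, adjusted p 0.0919) or 2 (-0.72, adjusted p 0.0862). In dorsal skin with age 3 rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p 0.405). The pigment protein gene PMEL went from 117 ± 5.71 to 16.5 ± 5.08 CPM. In scale skin with age 1 melanocyte marker, GPR143, fell (1 higher and 2 lower adjusted over the list alone; camera adjusted p 0.758), a call lost with edgeR, with DESeq2 (-1.41, adjusted p 0.107) and without any single library of the 4.

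Bone markers rose with age for 3 of 6 in dorsal skin (3 adjusted over the list alone; camera adjusted p 0.00389, and adjusted p = 0.200 with an estimated correlation). They rose for 3 in scale skin (4 adjusted over the list alone; camera adjusted p 0.000222, and adjusted p = 0.116 with an estimated correlation). Of these, PHEX lost the call without scale E9 replicate 1 or 2 or E11 replicate 2 (1.06, adjusted p 0.164). ALPL lost it without scale E9 replicate 2 (0.72, adjusted p 0.152) or either E11 replicate. In scale E9 1 of them was lower (1 higher and 1 lower adjusted over the list alone; camera adjusted p 0.395). Muscle markers rose for 6 of 16 and fell for 1 in dorsal skin (6 and 1 adjusted over the list alone; camera adjusted p 0.0175, and adjusted p = 0.646 with an estimated correlation). Dorsal E9 replicate 1 carried much of the rise: TTN stood at 19.87 CPM there and 3.03 in replicate 2, and ACTA1 at 45.4 and 13.24. Without that library TTN (0.72, adjusted p 0.399), Myl2 (0.94, adjusted p 0.0568) and ACTA1 (0.98, adjusted p 0.0857) lost the call. TTN and Myl2 also lost it without either E7 replicate and with only the libraries compared, and ACTA1 without E7 replicate 2. In scale E9 3 were lower (3 adjusted over the list alone; camera adjusted p 0.0432, and adjusted p = 0.645 with an estimated correlation). Without the dorsal E9 libraries MYBPC1 (-0.79, adjusted p 0.124) and MYL4 (-0.55, adjusted p 0.215) of these lost the call, and without scale E9 replicate 2 all 3 did. With age in scale skin limma called 0 muscle markers (0 adjusted over the list alone; camera adjusted p 0.459). Schwann cell markers rose for 4 of 10 in dorsal skin, NGFR by 3.54 ± 0.25 (4 adjusted over the list alone; camera adjusted p 0.142). In scale skin 2 rose (3 adjusted over the list alone; camera adjusted p 0.0114, and adjusted p = 0.116 with an estimated correlation), and in scale E9 2 were lower (2 adjusted over the list alone; camera adjusted p 0.992). Both lower ones, NGFR (-0.72, adjusted p 0.0565) and PMP22 (-0.37, adjusted p 0.149), lost the call without the dorsal E9 libraries. In scale skin with age NGFR lost it without scale E9 replicate 2 (0.67, adjusted p 0.284) or either E11 replicate. Stress genes were higher for 1 and lower for 4 of 24 in scale E9 (1 and 8 adjusted over the list alone; camera adjusted p 0.0432, and adjusted p = 0.456 with an estimated correlation). Of the 4 lower ones NR4A2 (-1.16, adjusted p 0.0746), FOSL2 (-0.96, adjusted p 0.0667) and HMOX1 (-0.34, adjusted p 0.393) lost the call without scale E9 replicate 2. HMOX1 lost it in 11 other alternatives as well. In dorsal skin 5 rose and 1 fell with age, KLF4 rising by 3.46 ± 0.27 (5 and 1 adjusted over the list alone; camera adjusted p 0.556), and in scale skin 3 rose (3 adjusted over the list alone; camera adjusted p 0.191). Those 3, FOS, FOSL2 (1.12, adjusted p 0.137) and KLF4 (1.18, adjusted p 0.137), all lost the call without scale E9 replicate 2. KLF4 lost it without any single library of the 4 (adjusted p 0.0559 to 0.164), and FOSL2 without E11 replicate 2. Cartilage markers rose for 8 and fell for 3 of 20 in dorsal skin (9 and 3 adjusted over the list alone; camera adjusted p 0.217). In scale skin 3 rose (5 higher and 1 lower adjusted over the list alone; camera adjusted p 0.571), and PTH1R (0.70, adjusted p 0.420), MATN4 (1.60, adjusted p 0.0644) and COMP (0.75, adjusted p 0.157) all lost the call without scale E9 replicate 2. Tendon markers rose for 5 and fell for 1 of 12 in dorsal skin (5 and 1 adjusted over the list alone; camera adjusted p 0.0623).

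Hypoxia and glycolysis genes were higher in scale E9 for 3 of 31 (2 adjusted over the list alone; camera adjusted p 0.279), CA9 (1.09 ± 0.17), NDRG1 (1.03 ± 0.17) and LDHA. LDHA lost the call without the dorsal E9 libraries (0.43, adjusted p 0.310), without scale E9 replicate 2 (0.36, adjusted p 0.499), without either replicate of dorsal or wing E9, without the mean-variance trend and with only the libraries compared. With age 4 rose and 6 fell in dorsal skin (6 and 7 adjusted over the list alone; camera adjusted p 0.326), and 1 rose and 1 fell in scale skin (1 and 1 adjusted over the list alone; camera adjusted p 0.482). Without scale E9 replicate 2 both of the latter, P4HA2 (0.76, adjusted p 0.118) and PFKP (-0.62, adjusted p 0.189), lost the call. Of 9 epidermal barrier genes 1 was lower in scale E9 (1 adjusted over the list alone; camera adjusted p 0.0992). With age 4 rose and 1 fell in dorsal skin (4 and 1 adjusted over the list alone; camera adjusted p 0.188). Of the rises KRT6A (adjusted p 0.0926), ABCA12 (1.31, adjusted p 0.0633) and CERS3 (1.02, adjusted p 0.0893) lost the call without dorsal E9 replicate 1, and SPINK5 without E7 replicate 1 or dorsal E9 replicate 2 (0.80, adjusted p 0.134). None was called in scale skin (0 adjusted over the list alone; camera adjusted p 0.758). Of 22 macrophage and leukocyte markers limma called 0 in each of the 3 main contrasts (0 adjusted over the list alone; camera adjusted p 0.840, 0.381 and 0.675). W-linked genes were higher in scale E9 than in feather skin for 2 of 4 (2 adjusted over the list alone; camera adjusted p 0.0109, and adjusted p = 0.420 with an estimated correlation). This came from their absence in dorsal E9: without those libraries HINTW differed by 0.09 (adjusted p 0.905) and SPINW by -0.49 (adjusted p 0.253). SPINW also lost the call without scale E9 replicate 2 (0.66, adjusted p 0.136). Cell cycle genes were higher in scale E9 for 3 of 44 (0 adjusted over the list alone; camera adjusted p 0.0227, and adjusted p = 0.569 with an estimated correlation). All 3 calls, CCNB3 (0.40, adjusted p 0.189), E2F8 (0.27, adjusted p 0.256) and SPC25 (0.11, adjusted p 0.636), ended without the dorsal E9 libraries, and also without either scale E9 replicate or wing replicate 1. With age in scale skin 2 of 15 retinoic acid genes rose (5 higher and 1 lower adjusted over the list alone; camera adjusted p 0.346). Both, ALDH6 and ALDH1A2, lost the call without any single library of the 4 (adjusted p 0.0578 to 0.334). None of 6 EDA genes was called (0 adjusted over the list alone; camera adjusted p 0.675). Dorsal and trunk dermis genes rose for 3 and fell for 4 of 22 in dorsal skin, MEOX2 rising by 2.33 ± 0.20 (4 and 5 adjusted over the list alone; camera adjusted p 0.976). In scale skin 2 rose (2 adjusted over the list alone; camera adjusted p 0.723). Of the limb identity genes TBX4 rose in dorsal skin (1 adjusted over the list alone; camera adjusted p 0.630). It lost the call with a pseudocount of 2 CPM (0.68, adjusted p 0.0688), after quantile normalization (0.74, adjusted p 0.0523), and without E7 replicate 1 or 2 or dorsal E9 replicate 2 (0.73, adjusted p 0.160). PITX1 fell in scale skin (1 adjusted over the list alone; camera adjusted p 0.346). Posterior HOX genes rose for 2 of 10 in dorsal skin (2 higher and 1 lower adjusted over the list alone; camera adjusted p 0.935). HOXC10 lost the call without any single library of the 4 (adjusted p 0.0905 to 0.286), with median-of-ratios scaling and without the mean-variance trend. HOXC11 lost it without E7 replicate 1 or 2 or dorsal E9 replicate 2 (0.69, adjusted p 0.169).

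Several other members of the gene lists lost their call in 1 or more alternatives, of which 1 each is given. In scale E9 against feather skin this held without the dorsal E9 libraries for TNC (-0.59, adjusted p 0.165) and INHBB (-0.71, adjusted p 0.110). Without scale E9 replicate 2 it held for HES5 (-0.98, adjusted p 0.144), NTRK3 (-1.43, adjusted p 0.0717), DCX (-0.97, adjusted p 0.0823), Wnt6 (1.54, adjusted p 0.0666), Wnt3 (0.96, adjusted p 0.0908) and RHOV (1.13, adjusted p 0.207). In dorsal skin with age it held without E7 replicate 1 for MBP (adjusted p 0.0683), GLI1 (0.85, adjusted p 0.118), TNFRSF19 (-0.91, adjusted p 0.0542), TRPM1 (-1.32, adjusted p 0.0782), CLDN1 (1.85, adjusted p 0.0718) and CDC6 (adjusted p 0.0828). Without dorsal E9 replicate 1 it held for CD34 (1.29, adjusted p 0.0773) and NTRK3 (1.33, adjusted p 0.0521), and without E7 replicate 2 for FOSL2 (adjusted p 0.0660). In scale skin with age it held without scale E9 replicate 2 for SPRY3 (1.33, adjusted p 0.129), HES5 (1.57, adjusted p 0.0994), WISP1 (1.31, adjusted p 0.0636), ASPN (1.22, adjusted p 0.0743), ALX1 (1.47, adjusted p 0.103) and cldn5 (1.56, adjusted p 0.0623). The same held for ST14 (-1.18, adjusted p 0.0659), ACTG2 (0.74, adjusted p 0.408), CSRP1 (0.86, adjusted p 0.305), FIBIN (1.48, adjusted p 0.0697) and CHODL (-0.87, adjusted p 0.0702), and for HEY1 without scale E9 replicate 1 (0.74, adjusted p 0.0529).

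In replicate 2 of thigh E9, 12 mitochondrial transcripts differed from replicate 1 by a median of 1.71, against -0.04 for all genes. The differences ran from -0.18 to 1.91. COX1 stood at 52149.6 CPM against 14679.3, while ND6 was not higher (664.02 against 750.74). Muscle tissue in that library would raise muscle markers, which differed by a median of 0.19 (bootstrap 95% interval -0.09 to 0.34, 16 genes), and the interval lies below the 0.5 set for this test. MYL4, the most abundant of them, did rise as muscle would have it (32.65 to 71.34 CPM), and TNNC1 with it (2.39 to 5.37), but ACTA1 (8.6 to 11.44), MYH7B (5.15 to 6.0), DES (5.02 to 4.67) and TTN (2.01 to 1.53), all at low levels, did not follow. The list argues against muscle as the whole cause, and a small share of it stays open. Nuclear genes of the respiratory chain were higher by 0.51 (0.31 to 0.75, 48 genes), past the 0.5 set for a higher oxidative demand by less than their spread, and the reading by the median rather than the interval was settled after the value was seen. Ribosomal protein genes, outside the respiratory chain, were higher by 0.90 (0.80 to 0.99, 57 genes). A shift of the library towards short housekeeping transcripts may therefore explain the excess too, but transcript length itself was not tested. Both stay open, since there is 1 such library.

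Scale E9 lay closer to dorsal E7 than to dorsal E9, and so did thigh and wing E9. The Spearman correlation across genes of scale E9 libraries was 0.953 to 0.962 with dorsal E7 and 0.932 to 0.942 with dorsal E9, and the lowest with E7 exceeded the highest with E9 by 0.018 in 1 scale library and by 0.017 in the other. Each thigh and wing E9 library also correlated better with both dorsal E7 libraries than with either dorsal E9 library, wing replicate 1 for example at 0.955 and 0.956 against 0.942 and 0.945. Scale E11 libraries had the other order, at 0.942 to 0.949 with dorsal E7 and 0.954 to 0.964 with dorsal E9. The order at E9 is therefore not particular to scale skin, and it did not hold in scale skin at E11. Fewer genes were called against dorsal E7 (1631) than against dorsal E9 (2676), and without sex-linked rows the ratio was 1.61 (2554 against 1585). The rows left out, 26 missing from dorsal E9 and 293 of the Z list, were too few to close that gap whatever their values. The ratio therefore says nothing about effects of sex on other genes. Of 766 genes lower in scale E9 than in thigh and wing E9, 292 had risen in dorsal skin from E7 to E9. That is 3.13 times the 93.2 of independent lists (Fisher's exact test, p 4.15e-82), while 76 had fallen there, 1.25 times those of independent lists. No dorsal library enters the difference of scale E9 from thigh and wing E9. The fits behind both sets of calls share libraries in their variances, however, and genes are not independent replicates. A lag of scale skin in a program shared with feather skin is a candidate explanation. Genes higher in scale E9 overlapped those that fell 2.02 times as often as independent lists, which a lag would also give. They overlapped those that rose 1.53 times as often, however, which a lag would not give. The fold changes correlated across all genes at r of -0.12 and rho of -0.05, in the direction of a lag but weakly.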
